A study of Mus musculus with 65 samples.

How the data were processed

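The series holds 65 samples of mouse cerebellum: 24 RNA-seq libraries (6 groups of 4), 18 H3K27ac ChIP-seq libraries (6 groups of 3) with 2 inputs, and MEF2A and MEF2D ChIP-seq libraries with 4 inputs that enter here as 2 peak lists. Groups were taken from the sample titles. Per the submitters' processing notes, STAR 2.6, Bowtie2 2.3.4.2 and MACS2 (without a version) were used with mm10, with no role stated for each. The counting tool and the filters are not given in the sources used here.

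The RNA table held log2 CPM values that the authors deposited per library, per the file headers and the values themselves. They carry a pseudocount of 0.5 reads, and whole reads could be recovered for 100% of values (tolerance 0.05 reads). Of 15560 entries, 91 repeated an Ensembl identifier and were dropped, which left 15469 genes. The same table held the authors' deposited log2 fold changes and adjusted p-values (p value after correction) for MEF2AD cKO against its Control and against the Controls of all lines. A sheet of the authors' deposited gene clusters repeated the per-library values in 82 columns that were not used. The authors' deposited rotarod sheet held a score per gene with a scale that is not stated, log2 fold changes of each knockout with a base read from the other sheet, and marks for peaks. The H3K27ac table held deposited read counts per site, without normalization, with the total of each library above them. The authors' deposited site lists held log2 values, each the logarithm of the mean of 3 ratios of cKO to Control reads per library total, and gave 188 compensatory and 1196 non-compensatory sites; 35 of the 1419 sites were in neither list. Classes were taken from the class column of the deposited count table, which marks 198 sites as compensatory and 1221 as non-compensatory; 198 of the former and 0 of the latter overlap a MEF2A peak, and 165 and 1221 overlap a MEF2D peak. The peak lists held positions without a score, per the file headers and values.

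RNA was tested with limma 3.58.1 (R 4.3.3): limma-trend on log2(CPM + 1) with 6 group means, moderated variances and the Benjamini-Hochberg threshold of 0.05. The design first assumed counts, and limma-trend was used because the design named it for normalized values. No filter was applied. The contrasts were each cKO against its own Control, the MEF2AD effect minus the MEF2A effect, minus the MEF2D effect, and minus the sum of both. Errors beside log2 folds are standard errors of the fit, and errors beside CPM are SD over libraries. H3K27ac counts were tested with edgeR 4.0.16 (quasi-likelihood, TMM over the sites, low-count filter of edgeR), which left 1372 sites. Class medians were compared by 100000 permutations of the class among sites. edgeR and DESeq2 1.42.0 were run on the recovered RNA reads as alternatives, with 15469 genes tested by edgeR. Independent filtering of DESeq2 left 7198, 4202 and 3 genes without an adjusted p in MEF2A, MEF2D and MEF2AD cKO. The fixed lists were tested with camera of limma, with the preset correlation of 0.01 and with an estimated one. The 24 lists are the MEF2 family, textbook MEF2 targets, activity-regulated genes, markers of mature granule neurons, of progenitor and immature granule cells, of Purkinje cells, of interneurons and unipolar brush cells, of astrocytes, of oligodendrocytes, of microglia, of endothelial cells, of choroid plexus, of brainstem and of red blood cells, genes of reactive glia, interferon response, heat shock and mitochondrial genes, potassium, sodium and calcium channels, glutamate and GABA receptors, synaptic vesicle genes, and Xist with Y-linked genes. Gene positions came from GRCm38.p6: 13660 genes matched by Entrez identifier, 1177 by symbol and 632 not at all, which left 14837 with a position. Peaks were assigned to genes they overlap or lie within 5000 bp of (bedtools 2.31.1), and Fisher exact tests used these genes. MEF2A peaks were shuffled 200 times within their chromosomes. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

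Named genes followed a rule set before the data were examined, as were the groups, contrasts, tests, gene lists and part of the alternatives. The rule takes the Mef2 genes, then genes with an adjusted p under 0.05, mean CPM of at least 1 and no overlap between replicates (12 largest falls, 8 largest rises), then up to 4 members per list. For H3K27ac it takes 5 falls and 5 rises, and for the rotarod sheet 5 genes each way. The rule for peaks, by score, could not be run. Some genes and sites that the rule gave are not reported here, though counts include them. Ttr, Igsf21 and the values of a gene in a comparison other than the one that named it were chosen after their values were seen.

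Recovered reads per RNA library ranged from 9178139 to 23160475. H3K27ac libraries held a median of 24 to 117 reads per site, so counting error is not small at the sites of MEF2AD cKO 3 and MEF2AD Control 3 (24 and 34 reads). Replicates varied by more than counting error: the lowest chi-square per degree of freedom between 2 replicates was 2.52 for RNA and 1.14 for H3K27ac. The share of genes without overlap between cKO and Control was 3.72%, 13.58% and 6.15% in MEF2A, MEF2D and MEF2AD cKO, against 2.86% by chance. Replicate numbers were checked as pairs: in RNA of line MEF2A, libraries of 1 number correlated at 0.386, 0.324, 0.210 and 0.163 and so were paired. In line MEF2D they correlated at 0.0306, 0.283, -0.0681 and 0.201 and in line MEF2AD at -0.133, 0.187, 0.359 and 0.250, and were not.

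The tests were tested on simulated data with known changes. For RNA (15469 genes), 2-fold changes were recovered in 78%, 82% and 84% of cases in MEF2A, MEF2D and MEF2AD cKO and 66% for the departure from the sum; 1.25-fold changes in 24%, 54%, 42% and 8%. False calls were 2.82%, 4.97%, 4.58% and 6.86% of calls. For H3K27ac (1370, 1364, 1360 and 1363 sites), 2-fold changes were recovered in 96%, 91.8%, 84% and 73.5% of cases, with 7.41%, 9.74%, 8% and 5% false calls. The simulated changes had random signs, most sites were left unchanged, and sites varied independently. These rates thus do not cover a shift shared by most sites or correlation between sites. In a simulated set test the shifted list had an adjusted p of 3.75e-102 (limma) and 0 of the other lists were called. The simulated genes varied independently of each other, so this says nothing on false list calls where genes are correlated. Alternatives tried were the scale and pseudocount, a CPM filter, limma without trend, edgeR and DESeq2, replicate blocks, sex as a covariate, other scalings and filters of the sites, other flanks and overlaps, and leaving out each library. Inputs entered only as a share of reads in sites, and the ChIP libraries of MEF2A and MEF2D were not analysed here beyond their peak lists.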

Results

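The study examined whether the paralogous transcription factors MEF2A and MEF2D depend on each other or stand in for each other in the mouse cerebellum, using conditional knockout (cKO) mice of 3 lines: MEF2A, MEF2D and both genes together (MEF2AD). RNA was measured in 24 libraries, 4 of cKO and 4 of Control mice from each line, taken at postnatal day 22 per the labels. H3K27ac, a histone mark of active promoters and enhancers, was measured by ChIP-seq in 18 libraries, 3 of cKO and 3 of Control mice from each line, with 2 input libraries. Binding was given as 1 list of 203 MEF2A peaks and 1 list of 1388 MEF2D peaks, without a score or a value per library. The 15469 genes of the RNA table held 9178139 to 23160475 reads per library. The H3K27ac libraries had 8694657 to 48557960 reads in all, of which 0.464% to 0.706% lay in the 1419 MEF2 sites that the deposited table covers. Each knockout had its own Control group, so the 3 knockout comparisons share no library. RNA changes, as log2 values or folds, are on log2(CPM + 1), which makes changes of genes at a few CPM smaller than the ratio of their mean CPM.

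Mef2a (ENSMUSG00000030557; mm10 chromosome 7, 67231163 to 67376456) checks the labels of 2 lines. Its normalised read count was 76.9, 97.8, 87.8 and 89.1 CPM in the MEF2A cKO libraries, against 207.3, 219.9, 229.7 and 231.8 CPM in their Controls. In the MEF2AD cKO libraries it was 89.4, 97.6, 88.4 and 99.2 CPM, against 188.4, 193.3, 193.0 and 181.7 CPM. Mef2a RNA thus fell by 1.33 (log2, SE 0.06; limma adjusted p = 5.4e-14) in MEF2A cKO and by 1.01 (SE 0.06; limma adjusted p = 1.69e-11) in MEF2AD cKO. Mef2d (ENSMUSG00000001419; chromosome 3, 88141941 to 88172091) did not fall in either line that targets it. It measured 363.3, 387.2, 359.5 and 360.2 CPM in MEF2D cKO against 356.7, 321.1, 310.3 and 305.7 CPM in its Controls (log2 fold 0.19, SE 0.08; limma adjusted p = 0.165). With replicate blocks or with only the groups of this line limma called it higher (adjusted p under 0.05 in both). In MEF2AD cKO it measured 387.7, 370.0, 363.7 and 360.9 CPM against 275.5, 302.4, 297.5 and 315.9 CPM, a rise of 0.32 (SE 0.08; limma adjusted p = 0.0170). That call was lost without MEF2AD Control 1 (0.28; limma adjusted p = 0.0780) and without MEF2AD cKO 1 (0.29; limma adjusted p = 0.0677). Counts over a whole gene can stay up when a deletion takes some exons, so RNA level did not check the Mef2d label. In MEF2A cKO, Mef2d measured 297.3 ± 39.3 CPM (SD, n = 4) against 298.0 ± 30.4, and in MEF2D cKO, Mef2a measured 231.8 ± 11.1 CPM against 210.3 ± 10.7; neither passed the test. Mef2c (43.1 ± 3.0 CPM in MEF2AD cKO, 38.4 ± 1.4 in its Controls) was not called in any comparison, and Mef2b was not in the table.

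**Figure D1:**
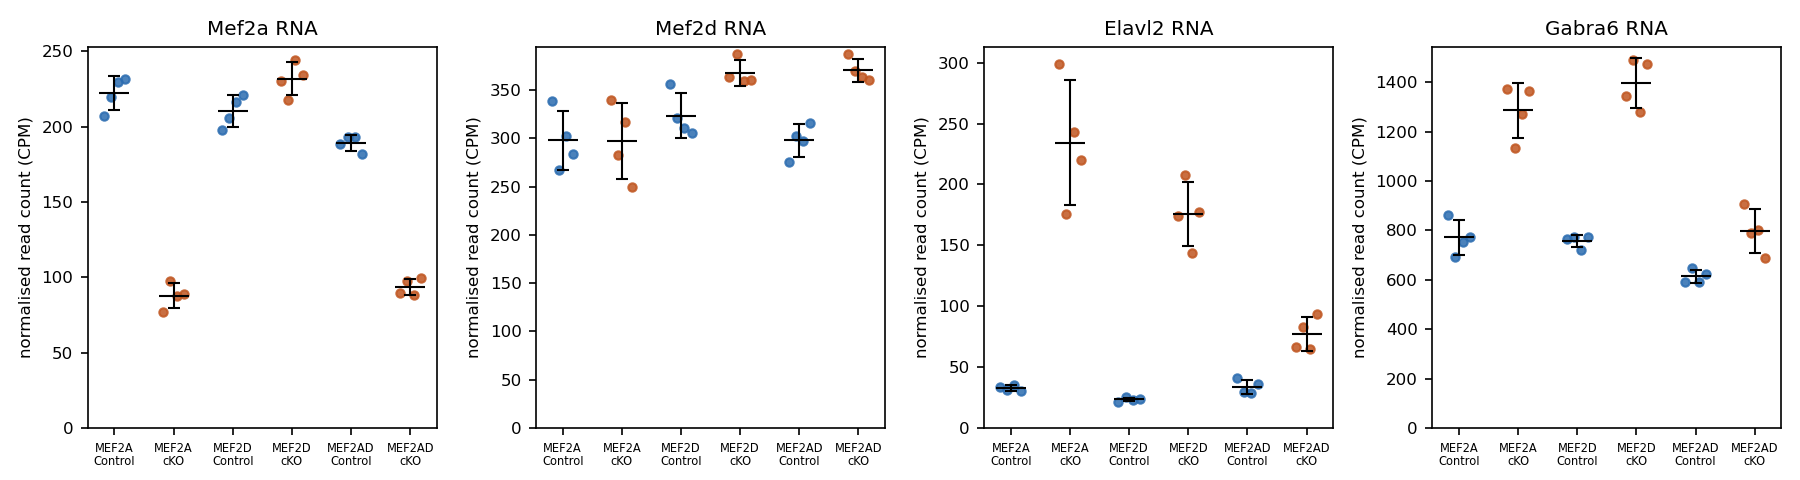
Normalised read count (CPM, linear axis from 0) of Mef2a, Mef2d, Elavl2 and Gabra6 in each RNA library, by line and genotype, with the mean and SD of 4 libraries as bars. Mef2a is lower in both lines that target it, Mef2d is in neither, and Elavl2 is higher in each single knockout than in the double knockout.

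The first comparison asked what the loss of MEF2A alone changed. Elavl2, which encodes a neuronal RNA-binding protein (ENSMUSG00000008489; chromosome 4, 91211533 to 91400108), rose 6.90-fold in MEF2A cKO, from 32.6 ± 2.3 to 234.4 ± 51.5 CPM (SD, n = 4). Gabra6, the GABA receptor subunit of mature granule neurons, rose 1.67-fold, from 771.6 ± 70.2 to 1286.0 ± 112.3 CPM. The potassium channel gene Kcnh3 fell by 1.24 (log2, SE 0.15; limma adjusted p = 3.73e-05), from 11.1 ± 1.5 to 4.13 ± 0.61 CPM, and Prom2, a membrane protein gene, fell by 1.13 (SE 0.11; limma adjusted p = 9.45e-07). The largest rise was that of 1700112J16Rik (ENSMUSG00000097527; chromosome 7, 67204082 to 67222536), by 4.1999 on log2(CPM + 1), from 0.370 ± 0.144 to 24.1 ± 2.1 CPM; it lies 8627 bp from Mef2a. Adamts17, a secreted protease gene 77992 bp from Mef2a, rose by 1.46.

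In all, limma called 44 of 15469 genes at an adjusted p of 0.05 in MEF2A cKO, 24 higher and 20 lower. The replicate numbers pair the libraries of this line, and with the pairs as a block the count was 116. With only the groups of this line it was 17. Without Control 3, cKO 1 or cKO 4 the count was 27, 25 or 23. Necab3 and Actl10, which overlap on chromosome 2, fell by 0.69 and 0.91; without strand in the counts their reads cannot be told apart. Spag17os fell by 1.002 and Tnn by 0.85. Of the 24 mature granule neuron markers, Gabra6 rose, 0 fell and 23 did not pass; 2 passed when adjusted over the list alone. Barhl1 rose among the 22 measured progenitor and immature granule markers (2 passed when adjusted over the list alone), a call that ended without Control 1, 3 or 4 or without cKO 1 or 3 (log2 fold 0.43 to 0.56 over the libraries left out; limma adjusted p up to 0.117). Kcnh3 was the 1 called member of 24 potassium channel genes (2 adjusted over the list alone).

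The second comparison asked what the loss of MEF2D alone changed. Elavl2 rose 7.21-fold in MEF2D cKO, from 23.4 ± 1.5 to 175.9 ± 26.0 CPM (SD, n = 4), and Gabra6 rose 1.84-fold, from 757.1 ± 25.3 to 1395.8 ± 101.0 CPM. Ccdc63, a gene for a cilium protein (ENSMUSG00000043036; chromosome 5, 122108052 to 122138080), fell by 1.94 (log2, SE 0.12; limma adjusted p = 1.8e-10), from 17.997 ± 1.411 to 3.96 ± 0.49 CPM. Igfbp5, which encodes a secreted binding protein of insulin-like growth factors (ENSMUSG00000026185; chromosome 1, 72858065 to 72874865), fell by 1.17 (SE 0.10; limma adjusted p = 7.48e-08), from 412.2 ± 26.0 to 183.0 ± 24.6 CPM. Prom2 fell by 1.74 and Kcnh3 by 1.22, as they also fell in MEF2A cKO. The collagen gene Col13a1, the glycosyltransferase gene Gcnt1, the channel-binding protein gene Kcnip2 and the adhesion gene Flrt3 fell by 1.38, 1.35, 1.27 and 1.13. Cda, the cytidine deaminase gene, rose by 1.57, the protease gene Pappa by 1.35 and Eya2 by 0.99 on the same log2 scale.

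In MEF2D cKO limma called 762 of 15469 genes, 401 higher and 361 lower, and 1385 with replicate blocks. Without Control 1, Control 3 or cKO 4 the count was 308, 490 or 331. Among the 24 mature granule neuron markers 2 rose, 4 fell and 18 did not pass (10 passed when adjusted over the list alone); Gabra6 rose, while Chn2 fell by 0.40 (SE 0.08) and Vsnl1 by 0.37 (SE 0.08). The vesicular GABA transporter gene Slc32a1, an interneuron marker, fell by 0.35 (SE 0.05; limma adjusted p = 2.54e-04), and 2 of 16 interneuron and unipolar brush cell markers fell with 0 higher (4 adjusted over the list alone). Of 24 potassium channel genes 1 rose and 3 fell (6 adjusted over the list alone), with Kcnh3 lower. Of 28 synaptic vesicle genes 4 rose and 0 fell (6 adjusted over the list alone), with Cplx2 up 1.32-fold from 1184.2 ± 42.1 to 1565.4 ± 61.5 CPM. Ccnd1 was 1 of 2 higher among 22 progenitor and immature granule markers (2 adjusted over the list alone), at 42.8 ± 1.3 against 31.01 ± 0.89 CPM. These counts moved when 1 library was left out: 1 to 3 mature granule markers rose and 2 to 5 fell, 0 to 2 potassium channel genes rose and 2 to 3 fell, and 1 to 2 progenitor markers rose. Of the synaptic vesicle genes 1 to 5 rose and 0 to 1 fell (1 rose without Control 1, cKO 1 or cKO 4). Of the interneuron markers 1 to 2 fell, as the call of Pax2 ended without any of 6 libraries (limma adjusted p up to 0.112).

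The third comparison asked what the loss of both proteins changed. Ccdc63 fell by 2.62 in MEF2AD cKO (log2(CPM + 1), SE 0.12; limma adjusted p = 4.85e-13), from 15.95 ± 3.26 to 1.73 ± 0.36 CPM (SD, n = 4). Igfbp5 fell by 1.74 (SE 0.10; limma adjusted p = 1.69e-11), from 343.5 ± 52.0 to 101.8 ± 14.7 CPM, and Gcnt1 fell by 2.29, the matrix protein gene Emilin3 by 1.96 and Prom2 by 1.55. The kinase-like gene Peak1 fell by 1.30, the membrane protein gene Xk by 1.22, the calcium release channel gene Ryr3 by 1.22 and the calcium sensor gene Ncald by 1.20. Elavl2 rose 2.25-fold, from 33.7 ± 5.7 to 77.0 ± 13.9 CPM, and Gabra6 rose 1.29-fold. The myosin gene Myo15 rose by 1.45 on log2(CPM + 1), from 8.93 ± 2.002 to 27.3 ± 10.1 CPM, the matrix gene Hmcn2 by 1.55, the protease inhibitor gene Serpinb2 by 1.44 and Fgd5 by 1.03. Both neighbours of Mef2a were again higher, 1700112J16Rik by 3.396 and Adamts17 by 1.39; neither was called in MEF2D cKO (log2 folds 0.01 and -0.02).

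limma called 374 of 15469 genes in MEF2AD cKO, 179 higher and 195 lower. The count was 632 with replicate blocks and 209 with only the groups of this line. Hdac9, a histone deacetylase gene and textbook MEF2 target, fell by 0.60 (SE 0.12; limma adjusted p = 0.0021); of the 15 measured textbook targets 2 fell, 0 rose and 13 did not pass (3 passed when adjusted over the list alone). Of the 24 mature granule neuron markers 3 rose, 1 fell (Vsnl1, by 0.52, SE 0.08) and 20 did not pass (6 adjusted over the list alone). Among 28 synaptic vesicle genes Cplx2 and Sv2c rose (1.61-fold and 1.46-fold), 0 fell and 26 did not pass (3 adjusted over the list alone). Of 33 measured activity-regulated genes 2 fell and 0 rose (3 adjusted over the list alone). When 1 library was left out, 0 to 2 of these fell (0 without cKO 3) and 0 to 1 rose, 1 to 2 textbook targets fell, 2 to 3 mature granule markers rose and 1 to 2 fell, and 2 to 3 synaptic vesicle genes rose and 0 to 1 fell. In the authors' deposited table, 430 genes had an adjusted p under 0.05 for the same comparison (211 higher, 219 lower), of which limma called 359 here. Against the Controls of all lines, the authors' deposited table had 719 such genes, 324 of them called by limma against the line's own Controls.

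**Figure D2:**
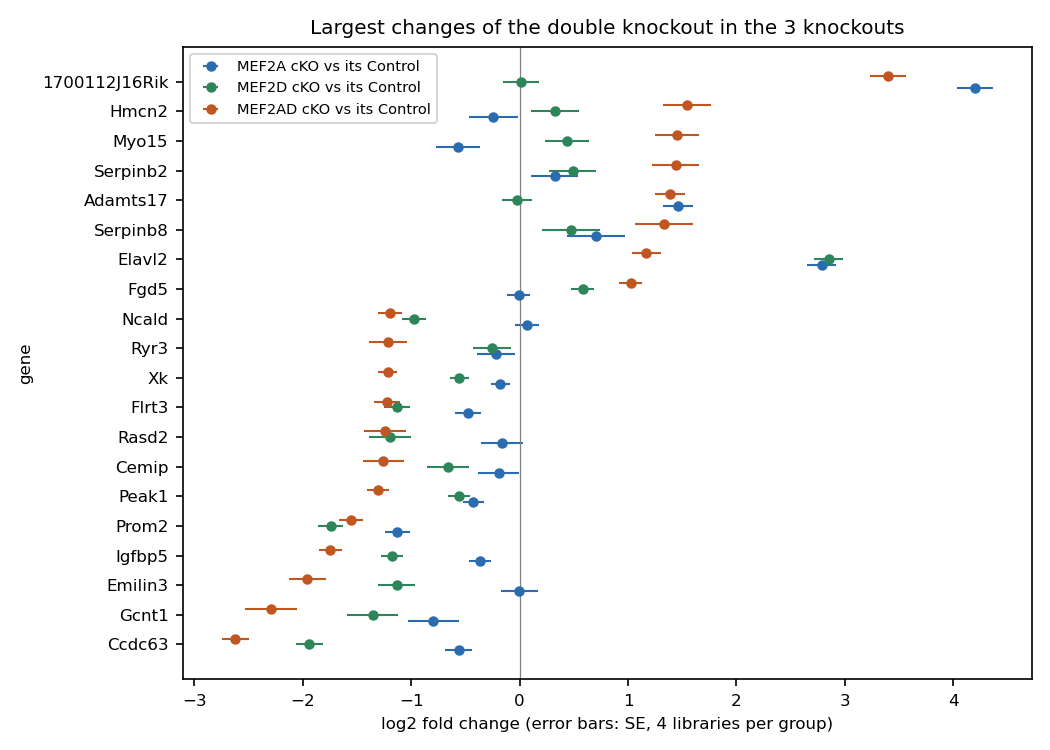
Change on log2(CPM + 1) with SE (4 cKO and 4 Control libraries per line) of the 20 genes with the largest changes in MEF2AD cKO that the naming rule gave, in each of the 3 knockouts. Ccdc63, Gcnt1, Emilin3 and Igfbp5 lie lowest in the double knockout, Elavl2 lies highest in the single ones, and 1700112J16Rik and Adamts17 are higher only in the lines that target Mef2a.

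The knockouts were compared to ask whether the genes that each paralog affects are the same. Elavl2, Gabra6, Kcnh3, Prom2 and Actl10 were among 32 genes called in both single knockouts, of which 18 were higher in both, 14 lower in both and 0 opposite; independent lists would share 0.622 and 0.467. Ccdc63, Igfbp5, Gcnt1, Emilin3, Rasd2 and Flrt3 were among 104 genes lower in both MEF2D cKO and MEF2AD cKO. Another 74 were higher in both and 1 went opposite ways, where independent lists would share 4.55 lower and 4.64 higher. MEF2A cKO and MEF2AD cKO shared 12 higher and 9 lower genes, with 2 opposite. Across 14665 genes, which are not independent replicates, fold changes correlated at Pearson r = 0.334 between MEF2A cKO and MEF2D cKO, 0.188 between MEF2A cKO and MEF2AD cKO and 0.462 between MEF2D cKO and MEF2AD cKO. The 195 genes lower in MEF2AD cKO had a median log2 fold of -0.48 there, -0.31 in MEF2D cKO and -0.10 in MEF2A cKO, and 87 of them were called in neither single knockout. The 179 higher genes had medians of 0.41, 0.25 and 0.07, and 102 were called in neither. These genes were chosen by their MEF2AD cKO change; the 361 genes lower in MEF2D cKO had medians of -0.29 there and -0.11 in MEF2AD cKO.

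Whether the double effect differed from a single one was tested directly. Igfbp5 was lower in MEF2AD cKO than in MEF2A cKO, by 1.38 (log2, SE 0.14; limma adjusted p = 5.21e-06), as were Ccdc63 (by 2.06), Emilin3 (by 1.95), Clic1 (by 1.45) and Ncald (by 1.27); Myo15, Hmcn2 and Synpo were higher by 2.02, 1.79 and 1.02. This difference was called for 85 genes, 36 higher and 49 lower; the count was 135 without MEF2AD cKO 4, 133 with DESeq2, 195 with replicate blocks and 54 with only the groups compared. Against MEF2D cKO, 16 genes differed, 3 higher and 13 lower; the count was 30 without MEF2AD cKO 4, 60 with DESeq2 and 71 with replicate blocks. The metalloprotease gene Tll1, the cell death gene Bmf, the chloride channel gene Clic1 and the phosphatase gene Dusp16 were lower in MEF2AD cKO than in MEF2D cKO by 0.98, 0.97, 0.95 and 0.95 (SE 0.13, 0.14, 0.16 and 0.15). Usp28 was lower by 0.61 and Prune2 by 0.47, and Synpo, which encodes an actin-linked synaptic protein, was higher by 0.68 (SE 0.10; limma adjusted p = 0.00112). Mef2a itself (-1.15), 1700112J16Rik (3.38) and Adamts17 (1.41) also differed. Elavl2 rose less in MEF2AD cKO than in MEF2D cKO (-1.68, SE 0.19) and than in MEF2A cKO (-1.62, SE 0.19).

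Departure from the sum of both single effects was tested next. A larger change than the sum could arise if a paralog covers for the other, and a smaller one if both act on the same step. Each effect came from its own line of mice, so a difference between lines cannot be told apart from these readings. Elavl2 departed most, by -4.47 (log2, SE 0.23; limma adjusted p = 5.12e-12): the single rises of 2.79 and 2.85 stood against 1.17 in MEF2AD cKO. Gabra6 also rose less than the sum (-1.25, SE 0.13), with 0.37 in MEF2AD cKO against 0.74 in MEF2A cKO and 0.88 in MEF2D cKO. Both genes thus rose less in MEF2AD cKO than in either single knockout, which neither reading foresees. Tll1, Dusp16, Bmf and Clic1 lay below the sum by 0.97, 1.13, 1.10 and 1.61: in MEF2AD cKO their log2 folds were -1.15, -0.84, -0.62 and -0.80, against -0.17, 0.12, 0.35 and 0.16 in MEF2D cKO and -0.01, 0.18, 0.13 and 0.65 in MEF2A cKO. The potassium channel gene Kcnq3 and the long noncoding RNA Snhg11 lay below the sum by 0.91 and 0.80, with log2 folds of -0.13 and -0.09 in MEF2AD cKO. Falls smaller than the sum were found for Kcnh3 (2.04, SE 0.26; limma adjusted p = 1.42e-04), which had a log2 fold of -0.41 in MEF2AD cKO, and for Prom2 (1.32). Kcnh3 too changed less in MEF2AD cKO than in either single knockout. limma called 55 genes, 22 above and 33 below the sum; edgeR called 42 and DESeq2 151, and limma with replicate blocks 180. The count moved between 26 (without MEF2D cKO 4) and 104 (without MEF2AD cKO 4), and reached 87 without MEF2A cKO 2. It was 28 without MEF2D Control 1; 31 without MEF2AD Control 1, MEF2AD cKO 2 or MEF2A Control 3; and 33 without MEF2AD cKO 3, MEF2A Control 4, MEF2A cKO 1, MEF2D Control 3 or MEF2D cKO 3. It was 35 without MEF2AD Control 4 or MEF2D cKO 1 and 36 without MEF2AD Control 3 or MEF2D cKO 2. Of the 195 genes lower in MEF2AD cKO, 9 departed from the sum, 11 from MEF2D cKO and 45 from MEF2A cKO.

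The fixed gene lists were compared with the other genes by camera, adjusted over 24 lists. Glutamate receptor genes had a median log2 fold of -0.10 in MEF2A cKO (24 genes, adjusted p = 5.83e-04, and adjusted p = 0.0310 with an estimated correlation), although 0 were called by limma, 0 when adjusted over the list alone. They lay above the sum of the single effects (median 0.22, adjusted p = 5.47e-06, and adjusted p = 0.00998 with an estimated correlation) and above the MEF2A effect in the difference of MEF2AD and MEF2A cKO (0.13, adjusted p = 6.1e-04, and adjusted p = 0.0299 with an estimated correlation). The MEF2 family list, 3 genes of which Mef2a was deleted, was lower in MEF2A cKO (adjusted p = 5.83e-04, and 0.0160 with an estimated correlation) and higher in the difference of MEF2AD and MEF2A cKO (0.00199 and 0.0299). Purkinje cell markers (median -0.07, adjusted p = 0.00553), potassium channel genes (-0.09, adjusted p = 0.00828), choroid plexus markers (0.81, adjusted p = 0.0472) and heat shock genes (0.14, adjusted p = 0.0472) passed in MEF2A cKO with the preset correlation alone. In MEF2D cKO oligodendrocyte (-0.15, adjusted p = 0.0110), interneuron (-0.12, adjusted p = 0.0119), glutamate receptor (-0.09, adjusted p = 0.0317), Purkinje cell (-0.10, adjusted p = 0.0317) and potassium channel lists (-0.09, adjusted p = 0.0388) passed with the preset correlation alone. By camera of limma, in MEF2AD cKO these were the oligodendrocyte markers (-0.19, adjusted p = 6.51e-05), synaptic vesicle genes (0.06, adjusted p = 0.00921) and textbook MEF2 targets (-0.12, adjusted p = 0.0345). Against the sum of the single effects, Purkinje cell (adjusted p = 0.0014), potassium channel (0.00472), interneuron (0.00482) and astrocyte lists (0.0186) were higher and choroid plexus markers (0.0106) lower with the preset correlation alone. In the difference of MEF2AD and MEF2A cKO this held for choroid plexus markers (0.00722) and textbook targets (0.0327), both lower. In the difference of MEF2AD and MEF2D cKO, glutamate receptor (0.00184), interneuron (0.0200), Purkinje cell (0.0438) and astrocyte lists (0.0438) were higher with the preset correlation alone. In each list that passed, the median, the mean and the test had the same sign.

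Lists of other cells or states did not pass camera of limma in any of the 3 knockouts for astrocyte (adjusted p = 0.245, 0.0620 and 0.838 in MEF2A, MEF2D and MEF2AD cKO), microglia (0.922, 0.343 and 0.419), endothelial (0.691, 0.499 and 0.756), brainstem (0.508, 0.821 and 0.599) and red blood cell markers (0.565, 0.821 and 0.756). The same held for reactive glia (0.819, 0.766 and 0.838), interferon response (0.691, 0.773 and 0.995) and mitochondrially encoded genes (0.444, 0.375 and 0.790), and for the list of Xist and Y-linked genes (0.965, 0.947 and 0.838). Mature granule neuron markers (0.691, 0.0891 and 0.838), progenitor and immature granule markers (0.691, 0.773 and 0.619) and activity-regulated genes (0.756, 0.527 and 0.838) did not pass as lists, nor did sodium and calcium channel (0.1003, 0.766 and 0.861) and GABA receptor genes (0.922, 0.317 and 0.204). Oligodendrocyte and interneuron lists had an adjusted p of 0.118 each in MEF2A cKO, and interneuron, Purkinje cell, potassium channel and glutamate receptor lists had 0.838, 0.878, 0.838 and 0.536 in MEF2AD cKO. In MEF2D and MEF2AD cKO, choroid plexus markers had 0.664 and 0.337, heat shock genes 0.821 and 0.723 and the MEF2 family 0.218 and 0.756. Synaptic vesicle genes had 0.0685 and 0.704, and textbook MEF2 targets 0.725 and 0.166, in MEF2A and MEF2D cKO. The choroid plexus gene Ttr ranged from 4.87 to 1674.6 CPM between libraries, and none of the 11 choroid markers was called by limma. Brainstem markers varied most in line MEF2AD, with a mean log2(CPM + 1) of 0.75 to 2.59 in Controls and 0.60 to 2.21 in cKO. In the other lines their mean was 0.40 to 0.89. The differences between the MEF2AD effect and the single effects were not adjusted for this.

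The authors' deposited sheets add a grouping of genes and a rotarod experiment. The authors' deposited table placed 305 genes in 4 clusters of 45, 85, 63 and 112, of which limma called 42, 71, 56 and 96 in MEF2AD cKO, all higher in clusters 1 and 2 and all lower in clusters 3 and 4. In the authors' deposited table all 305 had an adjusted p under 0.05 for MEF2AD cKO against the Controls of all lines. Against the line's own Controls 280 did. The calls, directions and MEF2AD cKO medians of these genes thus come from the same libraries and are no separate evidence. The 112 genes of cluster 4 had a median log2 fold of -0.54 in MEF2AD cKO, -0.26 in MEF2D cKO and -0.08 in MEF2A cKO. Fosb, Npas4, Fos, Nr4a3 and Nr4a2, genes that neurons switch on with activity, had the highest values in the authors' deposited table of 113 rotarod genes (2.15, 1.82, 1.69, 1.66 and 1.14, on a scale that is not stated). Nrcam, Dab2ip, Ypel2, Ppp6r3 and Sipa1l3 had the lowest values in the authors' deposited table (0.0988, 0.0990, 0.1001, 0.102 and 0.105). Of these 113 genes limma called 0 in MEF2A cKO, 15 in MEF2D cKO (14 lower, 1 higher) and 12 in MEF2AD cKO (11 lower, 1 higher). The sheet marks a MEF2D peak for 112 of the 113 genes and a MEF2A peak for 22, so these falls may be those of bound genes in general. Of 112 MEF2D cKO values in the authors' deposited table, 59 were below 0 (median -0.03), and their Pearson r with the values here was 0.219. Here 85 of 113 were below 0 in MEF2D cKO (median -0.09). For MEF2AD cKO 86 of 113 were below 0 there and 80 here (r = 0.717), and for MEF2A cKO 54 and 75 (r = 0.550).

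Binding was compared to ask whether both proteins share sites. Of 203 MEF2A peaks, 169 (83.3%) overlapped a MEF2D peak, whereas 167 of 1388 MEF2D peaks (12.03%) overlapped a MEF2A peak. MEF2A peaks placed at random overlapped a MEF2D peak 0.0700 times on average and at most once in 200 shuffles. The shuffles drew positions from whole chromosomes, so so low an overlap was fixed beforehand. They cannot tell sharing particular to these proteins from overlap of peaks in general. With at least 50% of each peak shared, 92 pairs remained, 45.3% of the MEF2A list and 6.63% of the MEF2D list. Both lists held a peak in Peak1, Bmf, Tll1, Jun and Mef2a or within 5 kb of them. The lists give no score, so weak and strong peaks were not told apart.

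Genes with a peak in the gene or within 5 kb were over-represented among called genes in MEF2D cKO and MEF2AD cKO. Mef2a carries both peaks, so the deleted gene is itself counted in MEF2A cKO and MEF2AD cKO. Ccdc63, Emilin3 and Peak1 carried a MEF2D peak and fell in MEF2AD cKO by 2.62, 1.96 and 1.30. Of 822 genes with a MEF2D peak, 132 (16.1%) were called in MEF2AD cKO, 100 lower and 32 higher, against 1.71% of the other genes (odds ratio 11.03; Fisher exact adjusted p = 7.51e-72). In MEF2D cKO 117 were called, 95 lower and 22 higher (odds ratio 3.50; Fisher exact adjusted p = 8.53e-25), and in MEF2A cKO 10 with Mef2a and Adamts17, 6 lower and 4 higher (odds ratio 5.22; Fisher exact adjusted p = 1.39e-04). Of 123 genes with a MEF2A peak, 26 (21.1%) were called in MEF2AD cKO against 2.34% of the others (odds ratio 11.2; Fisher exact adjusted p = 6.43e-17). Peak1, Tll1, the cell death gene Bbc3 (fell by 0.96), Dusp16 and Lzts2 (fell by 0.77) were among 25 that fell, and Olfm1 rose by 0.53; Lzts2 and Olfm1 were chosen after their values were seen. In MEF2D cKO 14 were called, 11 lower and 3 higher (odds ratio 2.44; Fisher exact adjusted p = 0.00643; 1.49 and 0.113 with a flank of 50 kb). In MEF2A cKO 2 were called, Mef2a and Igsf21 (odds ratio 5.92; Fisher exact adjusted p = 0.0494; 2.604 and 0.188 with a flank of 50 kb); as 1 of the 2 is the deleted gene, this says nothing beyond the deletion.

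**Figure D3:**
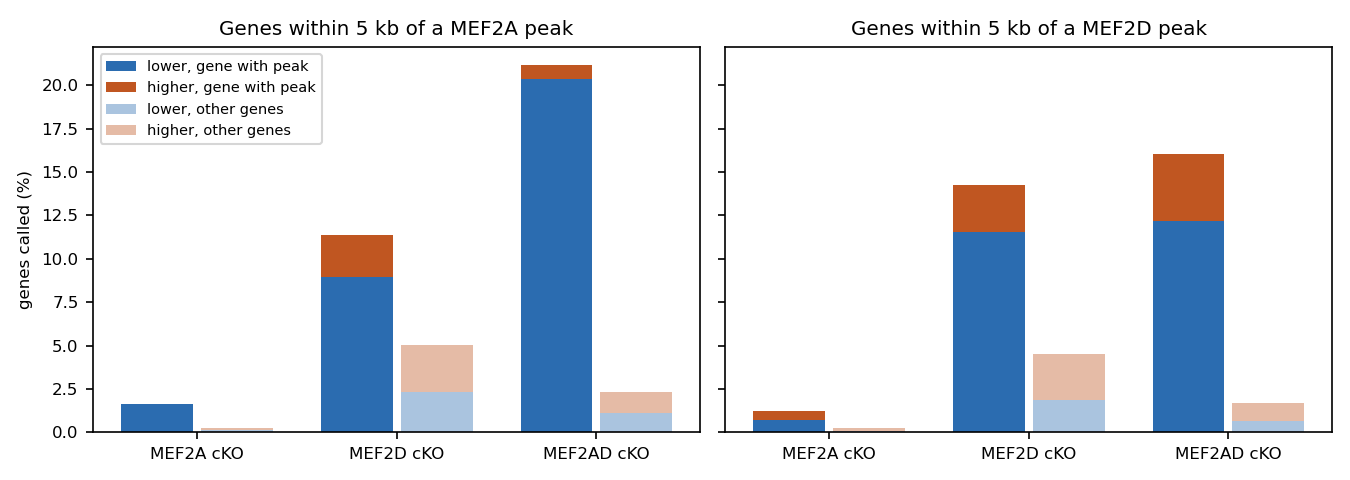
Percent of genes called lower and higher in each knockout, for genes with a MEF2A or MEF2D peak within 5 kb and for the other genes (14837 genes; 4 cKO and 4 Control libraries per line). The excess among bound genes lies mostly on the lower side in MEF2D cKO and MEF2AD cKO.

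H3K27ac was compared at 1372 MEF2 sites to ask whether loss of each paralog lowers the mark. A site in Zfp800 (chromosome 6, 28332603 to 28332864) was called lower in MEF2D cKO (edgeR adjusted p = 5.65e-09; log2 fold -4.18 to -3.49 when 1 library was left out), from 1.74 ± 0.36 to 0.0961 ± 0.0471 RPM (reads in the site per 1e6 reads of the library; SD, n = 3). It was also called lower in MEF2AD cKO (edgeR adjusted p = 4.57e-13), where too few reads were left to give a fold. A site in Tcf12 (chromosome 9, 71858021 to 71858350) was called lower in MEF2D cKO and MEF2AD cKO (log2 fold -4.39 to -3.27 and -4.57 to -3.62 when 1 library was left out), and sites in Rhot1 (-4.39 to -3.63) and 2810004N23Rik (-4.26 to -3.53) in MEF2D cKO. In MEF2D cKO all 4 sites had a mean of at most 0.2005 RPM, below the input median of non-compensatory sites, 0.239 RPM, so these folds rest on few reads. A site 37282 bp from Fos (chromosome 12, 85436014 to 85436608) rose by 1.27 in MEF2AD cKO (0.76 scaled to library totals), from 3.16 ± 0.26 to 5.67 ± 0.92 RPM. A site in Slit3 rose by 1.21 in MEF2D cKO and 1.246 in MEF2AD cKO (0.85 and 0.74 scaled to library totals).

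In MEF2D cKO edgeR called 475 sites, 201 higher and 274 lower, and in MEF2AD cKO 866, 424 higher and 442 lower. The split rests on the scaling: with library totals in place of TMM, 8 sites were higher and 565 lower in MEF2D cKO, and 28 higher and 753 lower in MEF2AD cKO, with medians over the sites of -0.36 and -0.51. The Zfp800 and Tcf12 sites were lower and the Fos and Slit3 sites higher under both. MEF2D cKO and MEF2AD cKO shared 260 lower and 179 higher sites, with 1 opposite (Pearson r = 0.875 across sites, which are not independent replicates); with library totals they shared 522 lower, 6 higher and 0 opposite. In MEF2A cKO 1 site was called, 18833 bp from Itprid2, higher by 1.21 (edgeR adjusted p = 0.0152). It was not called without MEF2A Control 2, Control 3 or cKO 3 (edgeR adjusted p up to 0.231), nor with library totals (0 sites called by edgeR, 138 at unadjusted p < 0.05) or DESeq2 (0 sites); 5 sites were called with replicate blocks and 10 with only the groups of this line. At unadjusted p < 0.05 edgeR gave 110 sites in MEF2A cKO. Departure from the sum of both single effects was called at 5 sites, all lower, but 6 of 100 regroupings of the libraries gave 5 or more (the highest other 790), so chance was not excluded. The count was 24 with library totals, 44 with replicate blocks and 3 to 34 when 1 library was left out.

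The authors divide the sites into a compensatory class, here 187 tested sites that all overlap a MEF2A peak, and a non-compensatory class, here 1185 sites without one. All 1185 overlap a MEF2D peak, and 23 of the 187 do not. Compensatory sites kept more of the mark than non-compensatory sites in MEF2D cKO and MEF2AD cKO. Their median log2 fold was 0.22 against -0.05 in MEF2D cKO (permutation p = 1e-05, the smallest they can give) and 0.25 against -0.06 in MEF2AD cKO (permutation p = 1.2e-04). Without the 23 sites the gap was 0.23 in MEF2D cKO and 0.31 in MEF2AD cKO. With library totals both classes fell, by 0.14 and 0.41 in MEF2D cKO and by 0.26 and 0.56 in MEF2AD cKO. Over cKO libraries the difference between classes was 0.245 ± 0.029 in MEF2D cKO, 0.310 ± 0.051 in MEF2AD cKO and -0.0315 ± 0.0388 in MEF2A cKO (SD, n = 3). The difference was thus no smaller where both genes were targeted than in MEF2D cKO. It therefore does not show that MEF2A held the mark at compensatory sites after loss of MEF2D. In MEF2A cKO the medians were -0.05 and 0.00 (permutation p = 0.00526). The permutation p-values of this comparison measure spread over sites, which are not independent replicates, and not over mice. In MEF2A cKO the difference over libraries was smaller than its SD, and MEF2A Control 1 alone gave -0.0424. With library totals 18.7% of compensatory and 44.7% of non-compensatory sites were called lower in MEF2D cKO, and 42.8% and 56.8% in MEF2AD cKO.

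**Figure D4:**
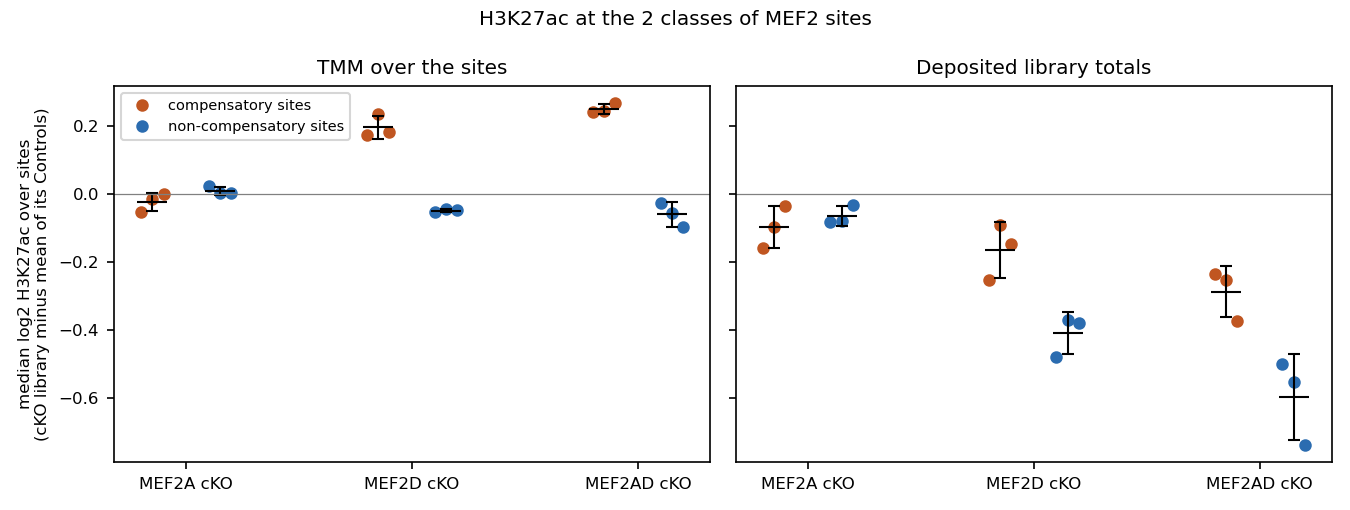
Median log2 change of H3K27ac at compensatory and non-compensatory sites in each cKO library against the mean of its Controls, scaled by TMM over the sites and by library totals, with mean and SD of 3 libraries. Compensatory sites lie above non-compensatory ones in MEF2D cKO and MEF2AD cKO under both scalings.

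H3K27ac changes were set against RNA changes of the genes that hold the sites or lie within 5 kb. In MEF2AD cKO the 122 sites at genes with lower RNA had a median log2 fold of -0.42 and the 37 at genes with higher RNA 0.37 (permutation p = 1e-05, the smallest they can give). With library totals these were -0.92 and -0.13. In MEF2D cKO the 118 and 27 sites had medians of -0.15 and 0.29 (permutation p = 0.00196), or -0.51 and -0.07 with library totals. These permutations too were over sites, which are not independent replicates. The sites that the authors' deposited table assigns to RNA clusters 2, 3 and 4 (9, 17 and 64 sites) changed by 0.09 ± 0.11, -0.78 ± 0.04 and -1.06 ± 0.36 in MEF2AD cKO with library totals (SD, n = 3). In MEF2D cKO they changed by 0.12, -0.49 and -0.52, and in MEF2A cKO by -0.04, -0.04 and -0.12. The rule that chose these sites is not stated, and the genes of these clusters were ones with changed RNA in MEF2AD cKO.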

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

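Among the tests of this part, those of scaling, of enrichment, of Elavl2 in MEF2AD cKO, of the sizes of its single rises and of the Mef2a neighbourhood were chosen after the result was seen. In 13 of 192 groups of 4 libraries a named gene had 1 library far from the other 3, where chance gives 9.6 (about 1 in 20). The gap over the range was 0.847 for Col13a1 in MEF2A cKO 3, 0.888 for Col13a1 in MEF2D cKO 4, 0.831 and 0.835 for Dnaja1 and Grin1 in MEF2D Control 1 and 0.862 for Gabra4 in MEF2AD cKO 3. It was 0.907 for Gabra6 in MEF2D Control 3, 0.936 for Galr1 in MEF2D Control 4, 0.906 for Ier5 in MEF2D cKO 1, 0.875 for Kcnh3 in MEF2D cKO 3, 0.857 for Mef2d in MEF2D cKO 2, 0.854 for Prom2 in MEF2AD cKO 1 and 0.849 for Wdfy1 in MEF2A Control 1.

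Effects differed between knockouts by a test of the difference itself for 55 genes (double effect against the sum), 85 genes (against MEF2A cKO) and 16 genes (against MEF2D cKO). For H3K27ac 5 sites were called against the sum, where chance was not excluded (6 of 100 regroupings). Nor was it for the 85 and 16 genes, where 4 and 3 of 100 regroupings gave as many or more. Elavl2 departed from the sum by -4.47 and 1700112J16Rik from the MEF2D effect by 3.38. Elavl2 rose in both single knockouts by nearly the same amount, and by less in the double one. Loss of a MEF2 protein may raise Elavl2, as MEF2AD cKO also rose (log2 fold 1.17). A transgene or linked variant in the single-knockout cKO mice may do so too, as both single rises were of 1 size (difference 0.0634, SE 0.19). Neither was excluded. A domain opened around Elavl2 cannot be told apart: 1 other tested gene within 1 Mb was called higher in both, Gm12653, which overlaps Elavl2, so no separate gene could have shown it.

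1700112J16Rik and Adamts17 rose in both lines that target Mef2a and neither was called in MEF2D cKO. An effect of the targeted Mef2a allele on its neighbours is a candidate explanation: among 9 other tested genes within 1 Mb, the largest log2 fold was 0.231. Lysmd4, the nearest tested gene at 2695 bp from Mef2a, did not rise (log2 fold -0.13 in MEF2A cKO and -0.15 in MEF2AD cKO). The rises thus did not follow distance to Mef2a alone. Whether loss of MEF2A protein raises both wherever they lie cannot be told apart, since 3 of 12 genes higher in both lines lay on chromosome 7 (one-sided Fisher exact p = 0.0567). As 2 of those 3 are the pair that prompted the test, and p was 0.544 without them, the test decides nothing.

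H3K27ac fell at MEF2 sites in MEF2D cKO and MEF2AD cKO with library totals and split into 201 higher and 274 lower sites in MEF2D cKO and 424 and 442 in MEF2AD cKO with TMM. TMM may hide a fall shared by most sites: every cKO library of these lines had a lower share of reads in the sites than every Control (smaller gap 0.0983 percentage points). The same held in line MEF2A, where 1 site was called with TMM. Its shares were 0.638%, 0.657% and 0.672% in cKO against 0.689%, 0.691% and 0.706% in Controls, so the separation was not particular to loss of MEF2D. The fall was larger in the other lines. Shares were 0.514% to 0.550% in MEF2D cKO against 0.648% to 0.693%, and 0.464% to 0.482% in MEF2AD cKO against 0.620% to 0.669%. Lower enrichment in the cKO libraries could lower that share, but as the whole cause it was argued against by the gap between site classes, 6.07 SD of the 3 cKO libraries at the least and 8.45 SD in MEF2D cKO. A higher starting level of compensatory sites was argued against only as the whole cause of that gap. Within 3 equal groups of sites by Control level, from low to high, the gap in MEF2D cKO was 0.554, 0.164 and 0.109, and in MEF2AD cKO 0.402, 0.304 and 0.0973. The high group held 91 of 187 compensatory sites and had the smallest gap, so starting level stays open as a part of the cause. A loss of the mark where MEF2D bound stays open, as does lower enrichment as a part of the cause.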

How the results depend on the processing

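Of the alternatives, those on the deposited log2 scale, edgeR, DESeq2, sex as a covariate, library totals, sites left out of the class lists, sites without a MEF2D peak, the shallowest libraries and the other flanks were chosen after seeing the data. Of 3882 alternative values of 183 named genes and sites, 3487 kept direction and side of the threshold, 391 lost the call, 4 gained it and 0 reversed. Of the 170 results with a call, 116 kept it under every alternative and 122 without any 1 library. The deposited log2 scale, a pseudocount of 0.1, a filter at 1 CPM, limma without trend, edgeR and sex as a covariate kept each RNA count within 1.5 times, and Mef2a kept its call in both lines under each alternative. With replicate blocks the RNA counts were 116 (MEF2A, from 44), 1385 (MEF2D, from 762), 632 (MEF2AD, from 374), 180, 195 and 71 (against the sum, MEF2A and MEF2D, from 55, 85 and 16), Mef2d in MEF2D cKO (0.19) was called by limma and the gene lists gave 15 calls in the 3 knockout comparisons. With only the groups of the contrast the counts were 17 (MEF2A), 209 (MEF2AD) and 54 (against MEF2A), and Mef2d in MEF2D cKO (0.19) was called. DESeq2 gave 151, 133 and 60 for the 3 differences. In the 3 knockout comparisons 2 of 14 list calls remained with an estimated correlation. Left-out libraries moved the RNA counts to 23 and 52 (MEF2A), 308 and 796 (MEF2D), 289 and 479 (MEF2AD), 26 and 104 (against the sum), 61 and 135 (against MEF2A) and 11 and 30 (against MEF2D), and Mef2d in MEF2AD cKO to 0.28 and 0.34.

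H3K27ac sites departing from the sum (5) numbered 32 with site totals, 27 with RLE, 25 without a filter, 24 with library totals, 29 without the sites in neither list, 44 with blocks, 12 without the 2 shallowest libraries and 3 to 34 without 1 library. For MEF2A cKO (1 site, 110 at unadjusted p < 0.05 in edgeR) they were 0 with library totals (138 at unadjusted p < 0.05 in edgeR), 0 with DESeq2, 5 with blocks, 10 with only its groups and 0 to 4 without 1 library. The class difference was 0.37 (MEF2D) and 0.40 (MEF2AD) as a mean over sites, against medians of 0.26 and 0.31. Without the 23 compensatory sites that overlap no MEF2D peak it was 0.231 in MEF2D cKO and 0.307 in MEF2AD cKO. Genes with a MEF2A peak within 50 kb had odds ratios of 2.604 (MEF2A cKO) and 1.49 (MEF2D cKO), no longer past the threshold. With 50% reciprocal overlap 45.3% of MEF2A and 6.63% of MEF2D peaks were shared. Where fewer libraries were used the power fell by construction. That cannot account for counts that rose, such as 104 RNA calls against the sum without MEF2AD cKO 4, from 55. The cause of these rises and of the other changes was not tested. Not run were the peaks with the higher scores (no score), a pseudocount of 0.1 for H3K27ac (values are counts), only the groups of the contrast for the departure from the sum in RNA (it uses every group) and RNA without a filter (the setting used). A departure of 2-fold from the sum was recovered in 66% of simulated RNA cases.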

Other observations

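The tests of genes with both peaks were chosen after the result was seen; the others in this part were set before. Genes bound by both proteins were lower in MEF2AD cKO against MEF2D cKO than genes bound by MEF2D alone. Among genes with mean CPM of at least 1, 114 had peaks of both MEF2A and MEF2D, among them Peak1, Tll1, Bmf, Jun and Mef2a itself, and 698 had a MEF2D peak alone. The median MEF2AD minus MEF2D effect was -0.05 at the former and 0.03 at the latter (permutation p = 1e-05, the smallest they can give). The MEF2D effect itself was -0.06 and -0.07 (permutation p = 0.646), and 11 and 23 of the 114 were called lower in MEF2D cKO and MEF2AD cKO, against 84 and 77 of the 698. The MEF2A effect was -0.04 and -0.03 (permutation p = 0.218), and the departure from the sum of the single effects -0.02 and 0.05 (permutation p = 0.00166). MEF2A may hold part of the expression of shared targets after loss of MEF2D, for which the differences between these 2 classes speak. It stays open, as at the 114 genes alone the MEF2A effect was nearly as large with MEF2D present. The shift is small, and nearby genes are not independent. These permutations were over genes, which share the same libraries and are not independent replicates, so their p-values do not measure spread over mice. Each effect also came from its own line of mice, so a difference between lines cannot be told apart.

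Genes with a MEF2D peak that were called in MEF2AD cKO fell more often than called genes without one (100 of 132 against 92 of 239; Fisher exact p = 4.17e-12). H3K27ac moved with the RNA of the same genes in MEF2AD cKO (permutation p = 1e-05, the smallest they can give). Compensatory sites had more H3K27ac than non-compensatory sites in Control libraries (median 5.31 against 3.80 RPM; permutation p = 1e-05, the smallest they can give). Both H3K27ac permutations were over sites, which are not independent replicates.

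Other splits of the libraries were refitted. For MEF2D cKO 1 of 35 splits, the real one, gave 762 genes and the highest other 2. For MEF2AD cKO 1 of 35 gave 374 and the highest other 247 (Controls 1, 3 and 4 with cKO 4). Chance is excluded at 0.05 for both but at no stricter level, as 1 of 35 is the smallest share these splits can give. In MEF2AD cKO the 247 calls of another split also point to a structure of the samples. For MEF2A cKO 2 of 35 splits gave 44 or more, so chance is not excluded at 0.05. The highest other gave 163 (Controls 1 and 2 with cKO 1 and 4), which points to a structure of the samples. Among the 8 splits that part all pairs the real one gave 44 and the highest other 0, but 8 splits cannot give a share under 0.05. For the departure from the sum 1 of 100 regroupings, the real one, gave 55 (highest other 13), so chance is excluded at 0.05. Against MEF2A 4 gave 85 or more (highest other 221) and against MEF2D 3 gave 16 or more (highest other 22). With 100 draws these shares are too near 0.05 to exclude chance, and some regroupings gave more calls than the real grouping. H3K27ac sites departing from the sum (5) were matched by 6 of 100 (highest other 790), so chance is not excluded. The 10 splits of H3K27ac in MEF2A, MEF2D and MEF2AD cKO cannot give a share under 0.05: the real split gave 1, 475 and 866 sites and the highest other 0 in each, in 1 split of 10 (edgeR).

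Per the labels the RNA libraries came from females, yet 7 of 24 had over 20 CPM of the Y-linked gene Ddx3y and under 10 CPM of Xist. These were MEF2A cKO 2 and Control 2 (Y-linked sum 244.1 and 257.9 CPM), MEF2D cKO 3 and Control 3 (183.9 and 178.1), and MEF2AD cKO 1, cKO 4 and Control 3 (217.1, 231.8 and 237.3). MEF2AD Control 4 had high Xist and a Y-linked sum of 15.4 CPM, where the next highest was 0.483. It also had 2.44 CPM of 1700112J16Rik, against 0.589 to 0.975 in the other MEF2AD Controls and 20.5 to 22.7 in MEF2AD cKO. The cause of both was not tested. Without this library limma called 375 genes in MEF2AD cKO, against 374 with it. The choroid plexus gene Ttr ranged from 4.87 CPM (MEF2A Control 1) to 1674.6 CPM (MEF2AD Control 3). The titles of the RNA libraries and the name of their sheet differ on whether the mice ran the rotarod or were at baseline.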
